A study of Homo sapiens with 2 samples.

How the data were processed

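Total RNA of 2 cultures labelled as FaDu, an established line of human head and neck squamous carcinoma cells, was hybridised to Affymetrix Human Transcriptome Array 2.0 microarrays. One array carried RNA of the untreated parental line and 1 array RNA of a line labelled as resistant to cetuximab, an antibody that binds the epidermal growth factor receptor. Per the labels' protocols, RNA was purified on columns with a DNase step, converted to biotin-labelled material and fragmented before hybridisation. The labels give neither the way resistance was obtained, nor the cetuximab dose, nor whether the drug was in the medium at harvest.

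The deposited values are log2 expression values of 67528 transcript clusters, the array's gene-level units, with 2 decimals and 1 column per array. The submitters' processing notes name Affymetrix Expression Console, and its version, the summarisation and normalisation algorithm and the genome build are not given in the sources used here. The unit was inferred from the values, which ran from 2.00 to 19.78 on the parental array and from 1.95 to 19.63 on the resistant array. The sorted values of the deposited columns differed by a median of 0.06 and at most 0.28 log2 units, so the arrays had been brought to nearly the same distribution before deposit. Such a step removes any difference in total RNA per cell and can compress or spread differences at the bright end. The table holds no probe intensities, detection calls or scan information, so array quality and scan batch could not be examined, and the precision is limited by the number of arrays.

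Gene names came from a platform annotation table that pairs clusters with symbols. It gave 1 symbol for 23781 clusters, several symbols for 1543 and none for 42204, and only clusters with 1 symbol were named. For 21497 of these the symbol was updated through the gene identifier to the RefSeq annotation of the assembly GRCh38.p14. That annotation was used for names and for the order of genes along chromosomes. The order rests on its start coordinates, which were used for nothing else. A gene with several clusters (479 genes) was represented by the cluster with the highest mean over both arrays, which left 22465 genes. Clusters of near-identical genes, such as those of the AKR1C, MAGEA, metallothionein, keratin and HLA families, may share signal through similar probes, and the values of their single members are uncertain. Clusters placed on chromosome Y are not reported.

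With 1 array per group there is no spread between replicates. No p-value is given, and differences are described by their size: the log2 value of the resistant array minus that of the parental array. Before the data were examined, the following choices were made. A gene was counted if the higher of its 2 values lay above the median of that higher value over all genes (5.98), and counted as different at 2-fold, a difference of 1 log2 unit. For 51 gene lists, the median difference of all measured members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart when its median lay outside the central 95% of the random medians, which chance gives for 2.5 of the 50 lists that had at least 3 measured members if genes are independent. The random lists do not keep the clustering of genes along chromosomes. In all, 1034 of 1191 list entries were measured. Coverage was lowest for mitochondrially encoded genes (0 of 13), histone genes (16 of 34), HOX genes (17 of 29), ribosomal protein genes (24 of 40) and basal keratinocyte genes (15 of 23). The differences of genes adjacent on a chromosome were correlated and compared with 1000 shuffles of the gene order, and medians were taken over windows of 25 adjacent genes. The genes named are the 12 largest positive and 12 largest negative differences among the counted genes, leaving out small noncoding, unnamed-locus, receptor-segment and Y-linked symbols, plus up to 4 members of each list with the largest absolute difference and EGFR.

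A background level was set after the data were seen, as the 95th percentile of 364 olfactory receptor genes, which most epithelial cells do not express. It was 5.09 on the parental and 5.03 on the resistant array. Where 1 array lay at or below it, the fold is given as "at least", computed from the background level, and where both did, no fold is given. The differences of these olfactory receptor genes had an SD of 0.42 log2 units over genes, which describes dim clusters and is not a replicate error.

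The alternatives were centring each array on its median, a loess correction of the differences on mean expression, quantile normalisation, the mean of all clusters of a gene, other brightness filters and size thresholds, unmatched random lists, and neighbours with related symbols left out. Raising values to background and leaving out chromosomes 14 and 18 were added after the data were seen. The scripts were tested on simulated data in which 200 of 22465 genes were changed over noise with an SD of 0.3. The size rule recovered 93 of 100 genes changed by 1.5 log2 units and 100 of 100 changed by 3, and counted 10 unchanged genes. A list shifted by 0.5 gave a median of 0.49. In 12 simulations without change, a mean of 2.9 of 50 lists lay outside the central 95%. The noise level was chosen, not estimated from replicates, and the noise was independent between genes. In the data, neighbouring genes were correlated and 30.0% of genes above the brightness level were at least 2-fold different. The simulated figures therefore give no error rate for these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.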

Results

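Expression of 67528 transcript clusters was measured in a line labelled as parental FaDu and in a line labelled as cetuximab-resistant FaDu, with 1 array for each. The deposited log2 values had a median of 4.79 over all clusters on the parental array and 4.72 on the resistant array. Of the 22465 named genes, 12957 lay above the background level on the parental array and 13063 on the resistant array. The design poses 1 question: which genes differ between the resistant line and the line labelled as parental. Neither line was replicated, so every difference below is between 2 arrays and carries no error across cultures. A difference cannot be assigned to resistance rather than to the culture, the passage or the array. That both cultures are FaDu rests on the labels alone. Another line or exchanged labels could not be excluded, as described for ME2 and SMAD4 at the end.

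The arrays differed widely. Across genes the values of both arrays had a Pearson correlation of 0.945, where genes are not independent replicates. Among 11224 genes above the brightness level, 1792 were at least 2-fold higher and 1578 at least 2-fold lower on the resistant array, together 30.0%. At 8-fold the counts were 243 higher and 164 lower. The median absolute difference of these genes was 0.60 log2 units.

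EGFR, the receptor bound by cetuximab (chromosome 7), was bright on both arrays and 2.28-fold higher on the resistant array, at 13.61 in the parental and 14.80 in the resistant line. Ligand genes of the wider EGF family, neuregulins included, went both ways. Of 9 measured EGF family ligands, 2 were at least 2-fold higher and 3 at least 2-fold lower. HBEGF stood at 6.88 on the parental and 10.57 on the resistant array, and TGFA at 7.01 and 8.74. EREG, the gene of epiregulin, stood at 12.06 and 7.45, and NRG4 at 8.99 and 6.25. The ligand list had a median difference of -0.08, inside the range of random lists, while over its 6 members above the brightness level the median was -1.10, outside that range.

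The largest positive differences included genes of secreted, adhesion and cytoskeletal proteins and of enzymes. SPP1, the gene of the secreted phosphoprotein osteopontin, was at background on the parental array and at 13.18 on the resistant array, at least 273-fold higher. CEACAM6, a cell surface adhesion molecule, was 396-fold higher, at 6.65 and 15.28. TGM2, the gene of transglutaminase 2, was 284-fold higher, and UCHL1, a deubiquitinating enzyme whose parental value (5.09) equalled the background level after rounding, at least 278-fold higher. NFE2L3, a transcription factor of the NRF2 family, was 249-fold higher. LCP1, an actin-bundling protein, was 185-fold higher, and FN1, the gene of fibronectin, 140-fold higher. INA, a neuronal intermediate filament gene, was 116-fold higher. ME2, the mitochondrial malic enzyme on chromosome 18, was at least 146-fold higher, the proteoglycan gene SRGN at least 132-fold, MARCHF4 at least 124-fold and the metalloprotease gene ADAMTS12 at least 106-fold.

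The largest negative differences included interferon-induced genes and genes of stratified epithelium. IFI27 stood at 14.84 on the parental array and at background on the resistant array, at least 895-fold lower. The interferon-induced genes IFI44, IFI6 and IFI16 were at least 245-fold, 322-fold and at least 60.8-fold lower. SLFN11, a gene known for its effect on sensitivity to DNA-damaging drugs, was at least 78.1-fold lower. DSC3 and DSG3, desmosomal cadherins of squamous epithelium, were at least 330-fold and at least 142-fold lower. The cadherin gene FAT2 was at least 107-fold lower, KRT4, a keratin of mucosal epithelium, 106-fold lower, and S100A2 104-fold lower. FOS, an immediate early transcription factor, was 258-fold lower, and the collagenase gene MMP13 at least 62.5-fold lower. Of the large folds given here and above without a lower bound, those other than CEACAM6 rest on a dimmer value below the 99th percentile of olfactory receptor genes (6.59 parental, 7.10 resistant) and are imprecise.

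**Figure D1:**
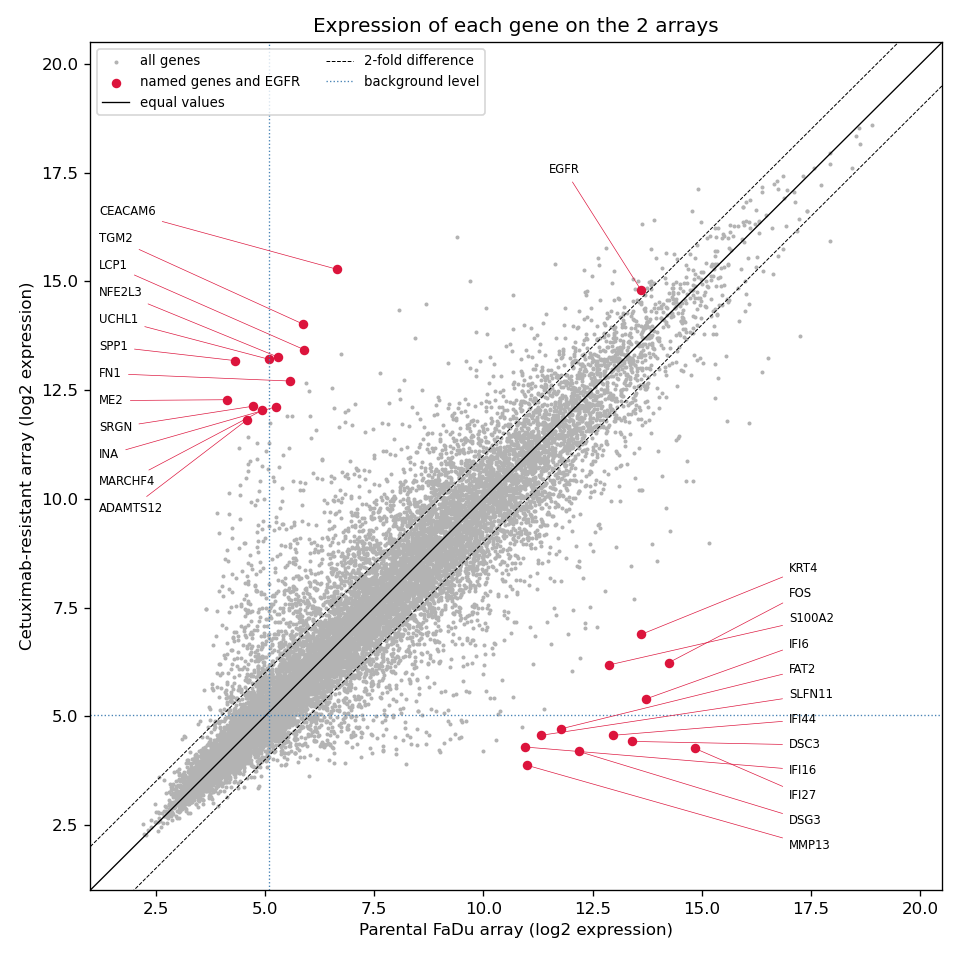
Log2 expression of each named gene on the parental array (x axis) and the cetuximab-resistant array (y axis), with 1 point per gene, dashed lines at a 2-fold difference and dotted lines at the background level of each array (5.09 and 5.03). The genes with the 12 largest differences in each direction and EGFR are in red, and EGFR lies just above the upper dashed line, while SPP1 and IFI27 lie at background on 1 array only.

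Of the 50 gene lists fixed in advance with enough measured members, 6 stood apart with lower values on the resistant array and 7 with higher values, against 2.5 in all by chance if genes were independent. Differences of neighbouring genes were correlated, so lists of clustered genes, such as metallothioneins (all 9 on chromosome 16), HOX genes and MHC class I genes (9 of 15 on chromosome 6), can lie outside the random range more often than that.

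Interferon-stimulated genes had the lowest median, -2.64 over 37 measured members, and 0 of 10000 random lists were as low. In this list 28 members were at least 2-fold lower and 0 at least 2-fold higher. OASL stood at 12.22 on the parental and 6.34 on the resistant array, besides IFI27, IFI44 and IFI6 above. Genes of MHC class I antigen presentation, which display peptides to cytotoxic T cells, had a median of -1.40, with 11 of 15 members at least 2-fold lower, 0 higher, and 0 of 10000 random lists as low. HLA-B stood at 10.64 and 8.38, HLA-C at 11.95 and 10.04, TAP1 at 8.06 and 6.26 and the peptidase gene ERAP2 at 11.88 and 9.71. MHC class II genes were near background on both arrays, with 2 of 10 above it on either array and a median of -0.06.

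Immediate early genes, which are induced within minutes by growth factors or stress and also by handling of cells, had a median of -1.36, and -0.80 with values raised to background. Of 23 members, 12 were at least 2-fold lower and 2 higher, and 0 of 10000 random lists were as low. EGR1 stood at 15.17 on the parental and 8.98 on the resistant array, FOSB at 12.03 and 6.04, and ZFP36 at 13.87 and 8.95. Metallothioneins, which bind zinc and copper, had a median of -0.93 with 4 of 9 at least 2-fold lower, and 24 of 10000 random lists were as low. MT1E stood at 10.76 and 8.69 and MT2A at 16.64 and 15.18. G2/M and mitosis genes had a median of -0.36 over 34 members, with 7 at least 2-fold lower and 1 higher, and 158 random lists were as low. AURKB stood at 11.48 and 10.06 and PRC1 at 13.43 and 12.02. HOX genes, which pattern the body axis, had a median of -0.36 over 17 members, with 97 random lists as low, and HOXD10 stood at 8.86 and 5.77. The HOX list did not stand apart with values raised to background or over members above the brightness level, with a median of -0.08 in both cases.

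MAPK pathway output genes, which are transcribed when ERK is active and include feedback inhibitors of the pathway, had the highest median, 1.61. Of 20 members, 13 were at least 2-fold higher and 2 at least 2-fold lower, and 0 of 10000 random lists were as high. PLAUR stood at 5.88 on the parental and 10.21 on the resistant array, and the ETS transcription factor gene ETV5 at 5.42 and 9.43. The members at least 2-fold lower were FOS and EGR1, which also belong to the immediate early list. ABC drug transporters had a median of 1.44, and 2.38 over the 8 members above the brightness level, with 6 of 11 at least 2-fold higher, 1 lower, and 1 of 10000 random lists as high. ABCC2 stood at 6.53 and 12.55, ABCG2 at background and 7.91, ABCC4 at 6.44 and 9.08, and ABCA12, a lipid transporter of keratinocytes, at 8.22 and background. NRF2 target genes, which serve antioxidant defence, had a median of 1.03, with 12 of 24 at least 2-fold higher, 0 lower, and 0 random lists as high. AKR1C2 was 6.48 log2 units higher, AKR1B10 stood at 5.54 and 11.16, AKR1C1 at 6.31 and 10.89, and ABCC2 also belongs to this list.

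YAP and TEAD target genes had a median of 0.75, with 9 of 23 at least 2-fold higher and 3 lower, and 0 random lists as high. NT5E, the gene of the ectonucleotidase CD73, stood at 8.43 and 13.71, ANKRD1 at background and 8.23, and TGFB2 at 6.31 and 10.46, while CCN2, a canonical target, stood at 10.16 and 5.42. Partial EMT genes of oral cancer had a median of 0.50, with 12 of 29 at least 2-fold higher and 6 lower, and 8 random lists as high. TIMP3, an inhibitor of metalloproteinases, stood at 5.93 and 12.67 and TGFBI at 8.47 and 11.97, while MMP1 and MMP10 stood at 9.44 and 7.70 on the parental array and at background on the resistant array. This list did not stand apart with the mean of all clusters of a gene, where its median was 0.15. Hypoxia response genes had a median of 0.46 (4 of 25 at least 2-fold higher, 3 lower, 103 random lists as high), with the glucose transporter gene SLC2A3 at 5.65 and 10.41. These 2-fold counts were near the shares over all genes above the brightness level (1792 higher and 1578 lower of 11224), so the hypoxia list stood apart by its median only. TGF-beta response genes had a median of 0.40 (8 of 21 higher, 3 lower, 70 random lists as high), with ID1 at 12.33 and 7.04, and it shares CCN2 and TGFB2 with the YAP list and TGFBI with the partial EMT list. The TGF-beta list did not stand apart without chromosomes 14 and 18, with a median of 0.30, and its median was 1.48 over the 14 members above the brightness level.

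**Figure D2:**
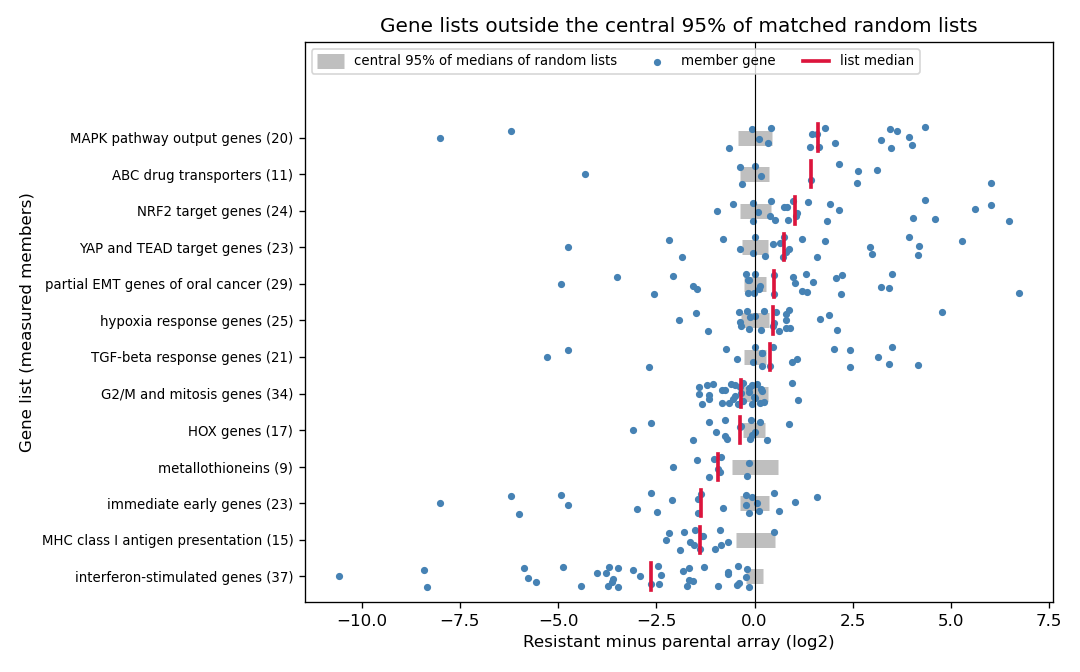
Differences of the resistant minus the parental array (x axis, log2) for the gene lists whose median lay outside the central 95% of 10000 matched random lists (y axis, measured members in brackets), with genes as blue points, list medians as red bars and the central 95% of random medians as grey bars. Interferon-stimulated genes, with a median of -2.64, and MAPK pathway output genes, with a median of 1.61, are at the ends.

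Markers of squamous epithelium were divided. Basal keratinocyte genes, of which 15 of 23 were measured, had a median of -0.43 and a mean of -1.13. Of these 15, 7 were at least 2-fold lower and 2 higher. As low were 467 of 10000 random lists, which is inside the central range, although the list lay outside the range of unmatched random lists. The basal keratin genes KRT14 and KRT5 stood at 11.39 and 5.17 and at 17.25 and 13.75, and BNC1 at 9.01 and background, while the integrin gene ITGA6 stood at 12.30 and 15.27. Squamous differentiation genes had a median of -0.05, and -0.45 over members above the brightness level, with 8 of 41 at least 2-fold lower and 4 higher. KLK10 stood at 10.24 and 5.41 and CSTA at 7.99 and background, while MAL stood at 5.80 and 10.38. Simple epithelial keratins had a median of 0.43 over 6 genes, and KRT7 stood at 8.73 and 11.51. Among S100 and alarmin genes (median 0.13, 4 of 15 higher, 1 lower), the protease inhibitor genes PI3 and SLPI stood at 9.39 and 16.03 and at 11.64 and 15.40.

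Epithelial junction and identity genes had a median of 0.07 and a mean of -0.44, with 7 of 28 at least 2-fold lower and 4 higher. Besides DSG3, the desmosome genes PKP1 and DSP stood at 8.52 and 5.50 and at 15.31 and 12.31. Mesenchymal and EMT genes had a median of -0.02 and a mean of 0.66, with 8 of 27 at least 2-fold higher and 1 lower. Over the 11 members above the brightness level the median was 1.32, and the list then stood apart. FN1 and TGFBI were the largest, SERPINE2 stood at 5.74 and 8.98 and COL6A1 at 6.30 and 9.09. Integrins had a median of 0.05, and 1.32 over the 11 members above the brightness level, where the list stood apart, with 7 of 20 at least 2-fold higher and 1 lower. ITGA2 stood at 9.69 and 15.02 and ITGB5 at 7.04 and 10.58. Collagens and laminins had a median of 0.06, and 0.32 over members above the brightness level (4 of 22 higher, 0 lower), with LAMA4 at background and 10.63. The metalloproteinase and plasminogen list had a median of -0.07, and -0.44 over members above the brightness level (4 of 21 higher, 7 lower), with MMP14 at 10.42 and 5.84.

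Lists of other receptors and signalling genes lay inside the random range over all measured members, but NOTCH, WNT and NF-kB genes stood apart over members above the brightness level, and checkpoint and NK ligand genes stood apart from unmatched random lists. Receptor tyrosine kinases had a median of 0.00, and 0.34 over members above the brightness level (5 of 29 higher, 2 lower), with the pseudokinase gene ROR1 at background and 10.68, EPHA4 at background and 8.33, and FGFR3 at 7.68 and 5.54. NOTCH pathway genes had a median of -0.04, and -1.65 over members above the brightness level (3 of 19 higher, 6 lower), with the feedback inhibitor gene NRARP at 12.78 and 7.87. WNT pathway genes had a median of 0.06, and 0.68 over members above the brightness level (4 of 24 higher, 4 lower), with LGR4 at 7.49 and 11.01 and RNF43 at 7.75 and background. NF-kB and inflammatory cytokine genes had a median of -0.10, and -1.07 over members above the brightness level (4 of 28 higher, 8 lower). IL1B stood at 10.39 and 5.13 and IL1A at 9.48 and background, while LIF stood at 5.34 and 9.78 and TNFAIP3 at 9.20 and 13.13. Immune checkpoint and NK ligand genes had a median of 0.24, and 0.47 over members above the brightness level (5 of 20 higher, 1 lower), with PVR at 8.27 and 10.94 and ULBP2 at 8.30 and 6.38.

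Apoptosis regulators had a median of 0.07, and 0.15 over members above the brightness level (5 of 25 higher, 4 lower). TNFSF10, the gene of the death ligand TRAIL, stood at 10.28 and background, its receptor gene TNFRSF10A at background and 9.23, and BCL2, which restrains apoptosis, was 3.17 log2 units higher. The p53 target list had a median of -0.03 (1 of 24 higher, 3 lower), with DDB2 at 10.45 and 8.11. G1/S and DNA replication genes had a median of -0.19 (3 of 32 higher, 5 lower) and stood apart only from unmatched random lists, with CCNE1 at 7.26 and 10.67 and TK1 at 12.75 and 10.64. Cell cycle inhibitors and cyclins D had a median of 0.02 and a mean of -0.24 (0 of 14 higher, 4 lower), with RBL1 at 11.85 and 10.31. Histone genes had a median of 0.26 (3 of 16 higher, 3 lower) and likewise stood apart only from unmatched random lists, with H2BC14 at 12.44 and 10.30. Stem cell associated genes had a median of 0.03, and 0.92 over members above the brightness level (4 of 16 higher, 2 lower), where the list stood apart, with SOX9 at 9.18 and 12.10, and CD44 at 13.62 and 16.32, while SOX2 had a difference of -2.28.

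Metabolic, stress and cancer-testis lists also lay inside the random range over all measured members, but fatty acid and unfolded protein response genes stood apart from unmatched random lists, and cancer-testis antigens over members above the brightness level. Fatty acid and lipid genes had a median of 0.21 (6 of 22 higher, 4 lower), with PPARG, the adipogenic nuclear receptor, at 5.21 and 10.40 and ACSL5 at background and 10.17. Cholesterol biosynthesis genes had a median of 0.09 (4 of 19 higher, 1 lower), with NSDHL at 8.13 and 11.72 and STARD4 at 9.61 and background. Xenobiotic metabolism genes had a median of 0.02, and 0.55 over members above the brightness level (3 of 22 higher, 3 lower), with GSTM3 at background and 9.33. Glycolysis enzymes had a median of 0.16 (2 of 17 higher, 2 lower), and nuclear genes of oxidative phosphorylation -0.12 (3 of 33 higher, 3 lower). ATF4 and amino acid response genes had a median of 0.09 (7 of 29 higher, 4 lower), with the cystine transporter gene SLC7A11 at 10.06 and 14.40 and WARS1 at 12.11 and 8.91. The unfolded protein response list had a median of 0.36 (3 of 19 higher, 2 lower) with SEL1L at 13.60 and 10.21, and heat shock genes 0.18 (2 of 15 higher, 0 lower) with HSPA4L at 8.82 and 11.51. Cancer-testis antigens had a median of 0.00, and 1.48 over members above the brightness level (4 of 19 higher, 1 lower), with MAGEC1 at background and 10.88 and PRAME at 7.78 and background.

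Most markers of other cell types were near background on both arrays, with exceptions. Of 11 fibroblast markers 3 lay above background on either array, of 15 leukocyte markers 3, of 10 endothelial markers 5 and of 9 melanocyte and neuroendocrine markers 2, with list medians of 0.00, 0.02, -0.02 and 0.00, where the endothelial mean was 0.22 and the leukocyte mean -0.05. At least 2-fold higher was 1 endothelial marker, PECAM1, at background and 5.17, close to the background level of the resistant array (5.03). At least 2-fold lower was 1 leukocyte marker, CD68, which many cell lines express, at 11.19 and 9.71. The fibroblast and the melanocyte and neuroendocrine lists had 0 in either direction. Ribosomal protein genes had a median of 0.03 (0 of 24 higher, 1 lower), and housekeeping genes -0.08 (3 of 21 higher, 5 lower). None of the 13 mitochondrially encoded genes of the last list had a named cluster.

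Differences ran along chromosomes. Over 10539 pairs of adjacent genes above the brightness level the correlation of their differences was 0.30, against a range of -0.03 to 0.03 in 1000 shuffles of the gene order. On chromosome 14, 178 of 359 genes were at least 2-fold lower and 19 at least 2-fold higher, with a median of -0.98. On chromosome 18, 69 of 167 were at least 2-fold higher and 16 lower, with a median of 0.66. Other chromosomes leaned less by median: 164 of 702 genes were higher and 25 lower on chromosome 19, and 172 of 712 and 63 on chromosome 2. On chromosome 17, 52 of 650 were higher and 132 lower, and on chromosome 16, 27 of 496 and 74. The window of 25 adjacent genes with the lowest median ran from SNW1 to CPSF2 on chromosome 14 (-3.05, 24 genes lower), and the next from RIN3 to SETD3 beside it (-2.43, 25 genes lower). Windows on chromosome 9 from SLC1A1 to PSIP1 and on chromosome 17 from ARHGDIA to FN3KRP had medians of -2.27 and -1.63. The highest window ran from LIPG to NEDD4L on chromosome 18 (2.17, 25 genes higher) and holds ME2. Windows from VGLL1 to ZNF185 on chromosome X and from PAIP1 to PLK2 on chromosome 5 had medians of 2.10 and 1.65. EGFR and the interferon-induced genes IFI44 and IFI6 lie on other chromosomes than 14 and 18, while IFI27 and FOS lie on chromosome 14 and DSC3 and DSG3 on chromosome 18. DSC3 and DSG3, with differences of -8.98 and -7.99, went against the higher lean of chromosome 18, as did DSC2 (-1.82) and DSG2 (-1.91) beside them. The neighbour correlation was still 0.27 without chromosomes 14 and 18, so a place elsewhere does not exempt a gene from the pattern.

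**Figure D3:**
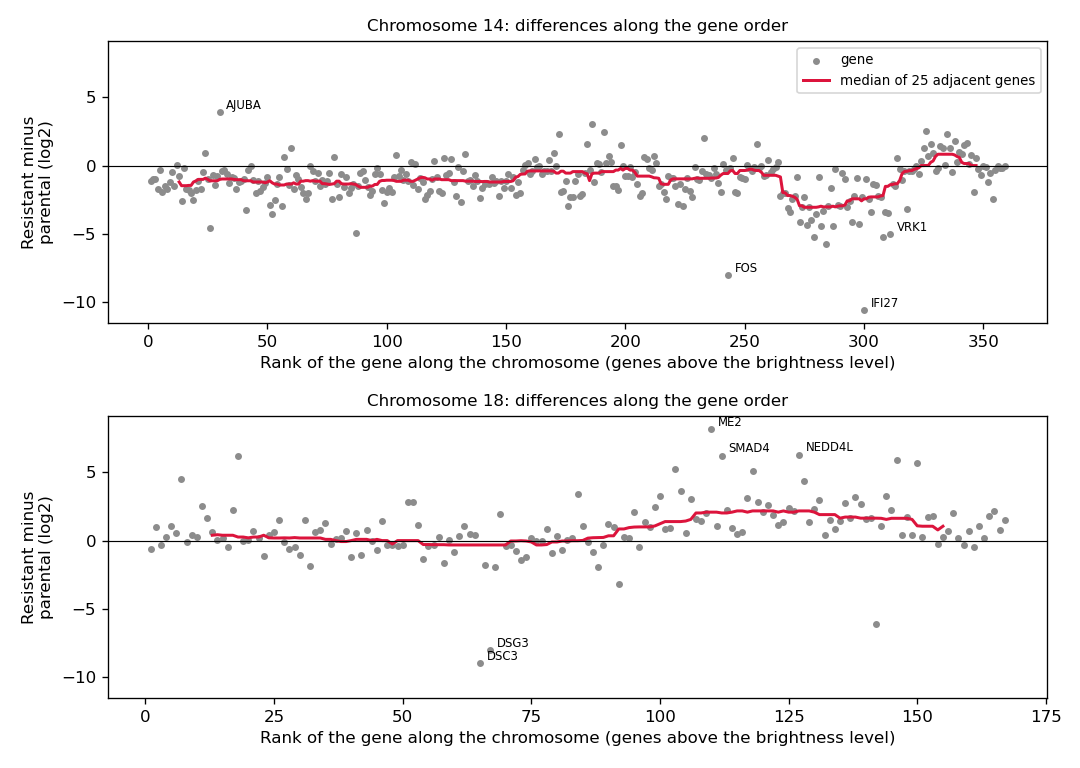
Difference of the resistant minus the parental array (y axis, log2) of each gene above the brightness level, by its rank along chromosome 14 (top, 359 genes) and chromosome 18 (bottom, 167 genes). The red line is the running median of 25 adjacent genes, which is lowest near the SNW1 to CPSF2 window on chromosome 14 (median -3.05) and highest near the LIPG to NEDD4L window on chromosome 18 (2.17).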

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

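Clusters without a listed gene symbol were outside the comparisons above. Of 42001 such clusters not placed on chromosome Y, 10589 lay above the brightness level, and 1106 of these were at least 2-fold higher on the resistant array than on the parental array, which drew attention as signal in data not otherwise used. Another 1986 were at least 2-fold lower, so lower values outnumbered higher ones, the reverse of the named genes (1792 higher, 1578 lower). The clusters without a symbol have no name here and no biological explanation was tested.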

How the results depend on the processing

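With 1 array per line no replicate could be left out, and no error across cultures can be given. No paired analysis was possible because each line has a single array. Raising values to background and leaving out chromosomes 14 and 18 were chosen after the data were seen. Direction and approximate size held for the counts of named genes under centring, loess, quantile normalisation, mean of clusters, no brightness filter, values raised to background and omission of chromosomes 14 and 18, with 1704 to 1983 genes higher and 1384 to 1662 lower. Quantile normalisation moved the median of the brighter genes from 0.01 to 0.11. By construction the counts moved with the 75th percentile filter (1067 higher, 958 lower), a 1.5-fold threshold (2926 and 2774) and a 3-fold threshold (945 and 726). The number of lists standing apart with higher values went from 7 to 12 of 45 when only members above the brightness level entered and to 11 of 50 with unmatched random lists, and the number with lower values lay between 5 and 8. All lists that stood apart kept the sign of their median under all 8 alternatives. Of these, 10 stayed outside the central range throughout, and HOX genes, partial EMT genes and TGF-beta response genes did not. The neighbour correlation was 0.22 to 0.30 under its 4 alternatives. The differences of EGFR and the 24 other genes named by size kept their sign and their side of 2-fold under all 6 alternatives run on them, which leave out those on chromosomes 14 and 18 in 1 case. Values near background limit the fold of dim genes, and the deposited table has no detection calls.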

Other observations

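The genes in this paragraph were chosen after their values were seen. On chromosome 14, each of 49 consecutive genes above the brightness level from CEP128 to CCNK was lower on the resistant array, 43 of them at least 2-fold, with a median of -2.89. The 20 genes before this stretch had a median of -0.24 and the 20 after it -0.08. The stretch holds TRIP11 (13.45 and 7.69), VRK1 (14.27 and 9.25) and ATG2B (12.33 and 7.14). On chromosome 11, PPFIA1 stood at 15.58 on the parental and 11.79 on the resistant array, CTTN, the actin regulator cortactin, at 16.51 and 13.23 and FADD at 11.70 and 9.10, while their neighbours CCND1 and ANO1 stood at 14.85 and 14.19 and at 10.97 and 13.42. The 22 mitochondrial clusters had a median difference of -0.05.

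The tests on ME2 and SMAD4, on chromosome medians and on the shift of genes by scaling were chosen after the values, or the windows on chromosomes 14 and 18, had been seen. The differences of neighbouring genes went together. Probes or transcripts shared between overlapping or related neighbours would act mainly on genes close together. Yet the correlation was 0.14 for genes 10 apart, above the highest of 1000 shuffles (0.03). It was 0.28 for adjacent genes whose symbols began differently. That rule keeps pairs such as CHD8 and the small RNA gene SNORD9, and long runs of related genes may reach further, so a part of the correlation may still come from sharing. Centring, loess and quantile normalisation moved the difference of any gene above the brightness level by at most 0.20, while the lowest window had a median of -3.05. The deposited arrays already had nearly the same distribution, so such scalings could move little. They do not test the normalisation done before deposit, whose part in the pattern stays undecided. Unequal copy number of chromosome segments in the 2 cultures may account for the pattern, as may chromatin domains, and these cannot be told apart because no DNA was measured. The largest chromosome median was 0.98 in size, against at most 0.28 in 1000 shuffles of genes over chromosomes. It is that of chromosome 14, whose windows had prompted the test, so it decides nothing by itself. Chromosomes 18, 19 and 4, with medians of 0.66, 0.39 and 0.35, also exceeded 0.28, and of the chromosomes with negative medians only chromosome 14 did. The shuffles break the correlation of neighbours, so such medians do not tell a shift of a whole chromosome from shifts of parts of it.

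ME2 and its near neighbour SMAD4, the common mediator of TGF-beta signalling, were at background on the parental array (4.12 and 4.60) and bright on the resistant array (12.28 and 10.81). The smaller of the measured differences, that of SMAD4, had a lowest value of 6.18 under 3 scalings. From the background level it was 5.72 in the deposited values. As above, these scalings could move little and do not test the normalisation done before deposit. Among 6579 protein-coding genes whose higher value was above 8, 3 adjacent pairs were at background on the parental array only. The other pairs were CPPED1 with SHISA9 and TNFRSF10D with TNFRSF10A. Shuffles gave a mean of 0.49 such pairs and at most 4. The observed 3 pairs lay above that mean but inside the range of shuffles, so the count cannot say whether ME2 and SMAD4 stand apart. Pairs were adjacent among these 6579 genes only, which leaves out ELAC1 (6.17 on the resistant array) between ME2 and SMAD4. A segment missing from the parental-array cells only is a candidate explanation: ELAC1, between them, stood at 5.10 on the parental array, just above the background level (5.09), and no DNA was measured. A lost segment could not be regained, so the resistant culture would then stem from cells that never lost it, from another line, or the labels would be exchanged; with 30.0% of the 11224 genes above the brightness level at least 2-fold different and no genotype in the table, these cannot be told apart.

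The median of the interferon-stimulated list stayed at or below -2.57 under 3 scalings, which again could move little and do not test the normalisation done before deposit. Copy number of the surroundings of these genes is argued against: 29 of 30 members above the brightness level were lower than the median of their nearest neighbours, and member minus neighbours had a median of -3.47. Whether the parental culture was exposed to an interferon signal or the resistant line lost its response stays open, as does a difference between the lines themselves, and none of these was tested.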
